A study of Homo sapiens with 16 samples.

How the data were processed

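The series holds polyA RNA sequencing of VCaP cells in 8 groups of 2 libraries, 16 in all: Vc or Ver, each with control medium, DHT, enzalutamide, or DHT plus enzalutamide. Cells were kept 4 months in ethanol (Vc) or 1 µM enzalutamide (Ver), starved for at least 48 h in phenol red-free medium with charcoal-stripped serum, and treated for 24 h. The authors deposited, for each library, a file of read counts per gene, whose unit is the count. The authors also deposited 1 table with a normalized signal per gene and library. That table was checked against the counts: its values equal the counts divided by DESeq2 size factors, and it was used only for gene names. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.36-5, HISAT2 and SAMtools (no versions given) and HTSeq 0.11.1, with GRCh38 as the genome. The names of the count files give unstranded counting in union mode, so reads of overlapping and antisense genes cannot be assigned with certainty.

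The 5 summary lines of each count file were set aside. The files list 58302 genes, of which 40888 had a count. Positions and missing names came from GENCODE release 29, which holds 58039 of the gene identifiers. Gene totals ran from 8155244 to 13273523 counts per library. Reads in no gene made up 45.0 to 50.6% of the counted reads, and ambiguous reads 7.09 to 8.55%. The share in no gene differed by treatment and line: it was 50.4 ± 0.342% in control and 47.0 ± 0.130% with DHT in Vc, 48.8 ± 0.250% and 45.4 ± 0.213% in Ver, and with both compounds 48.3 ± 0.445% in Vc and 45.5 ± 0.670% in Ver (mean ± SD, n = 2). Whether this affects the results was not tested.

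Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (22553 genes), scaled by TMM, and fitted with the robust quasi-likelihood model over all 16 libraries and 8 groups (8 residual degrees of freedom; common biological coefficient of variation 6.01%). The two-sided quasi-likelihood F test was run for 12 comparisons: DHT, enzalutamide, and enzalutamide on top of DHT in each line, the difference of each between the lines (Ver minus Vc), DHT plus enzalutamide against control in each line, and Ver against Vc untreated. Ver against Vc was also counted under the other treatments. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p given for a gene is from this test unless another tool is named. The SE of a log2 change is its Wald standard error from the fitted quasi-likelihood variance, or from Poisson counting where that is larger. Expression is given as CPM, edgeR's scaled counts with TMM-adjusted library sizes. The principal components used log2 CPM with a pseudocount of 2. Tested on simulated data with the depth and spread of these libraries, the DHT comparison in Vc recovered 35.8%, 53.7% and 84.8% of genes changed 1.5-fold, 2-fold and 4-fold. A difference between the lines was recovered in 23.9%, 43.3% and 71.2%. False calls were 8 and 3 genes. Each simulation changed only 67, 67 and 66 genes by these folds, and changed genes dropped by the filter counted as missed. Far more genes were called for DHT in the data, so the adjusted cutoff was stricter in the simulation. Its shares and false calls are therefore not those of the real DHT comparison.

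In all, 24 gene lists were written from general knowledge: androgen-induced genes, androgen-repressed genes, UGT2B glucuronidation genes, androgen synthesis and metabolism genes, steroid receptors, glucocorticoid receptor target genes, DNA replication and G1/S genes, mitosis genes, cholesterol synthesis genes, fatty acid synthesis genes, neuroendocrine and neural genes, epithelial and luminal genes, basal prostate genes, mesenchymal transition genes, interferon response genes, endoplasmic reticulum stress genes, hypoxia and glycolysis genes, polyamine and prostate secretory genes, drug efflux and xenobiotic genes, WNT and stem cell genes, stromal and endothelial marker genes, immune marker genes, mitochondrially encoded genes and heat shock genes. Lists with at least 3 tested members (23) were compared with the other genes by camera of limma 3.58.1, two-sided, with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 276 tests. Members were counted from the calls over all genes and from p-values adjusted over the list alone. 3 genes are in more than one list: FKBP5, SGK1 and ZBTB16 are in both the androgen-induced and the glucocorticoid receptor target lists. Genes were named by a rule: KLK3, KLK2, TMPRSS2, FKBP5, ERG, NR3C1, UGT2B15, UGT2B17, MYC and others not reported here in any comparison; the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean of at least 5 CPM; the 4 members of each list with the smallest adjusted p; and list members asked for by a count of 5 or fewer. From these, the text names a part.

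The comparisons, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0 with its Wald test, DESeq2-type (RLE) size factors in edgeR, no filter on low counts, a fit on only the groups of a contrast, replicate numbers as a block within each line, and leaving out each library in turn, where the lone library of a group is assumed to vary like the other groups. For lists they were an estimated correlation, fry and the same block and filter. Leaving out each library for the list test, and counting Ver against Vc outside shifted chromosome windows, were added after the data were seen. Windows of 10 Mb were used with at least 15 genes of at least 2 CPM. With 2 libraries per group, no test of single outlying libraries and no regrouping of libraries was made.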

Results

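VCaP is a human prostate cancer cell line with a fusion that puts the ERG gene under the androgen-driven TMPRSS2 promoter. The series asks how VCaP cells kept for 4 months in 1 µM enzalutamide, an antiandrogen drug (Ver), differ from VCaP cells kept for 4 months in ethanol (Vc). Both lines were starved of steroid hormones for at least 48 h. They then received control medium, 1 nM of the androgen dihydrotestosterone (DHT), 1 µM enzalutamide, or DHT plus enzalutamide for 24 h. The androgen dominated the transcriptome: the first principal component of log2 CPM held 44.6% of the variance and set the DHT libraries apart from the controls in both lines. The second held 15.3% and separated Vc from Ver. Each group had 2 libraries (n = 2), and the labels do not say whether these were separate cultures. Vc and Ver are 1 line each, so p-values for differences between them measure spread between libraries, not between lines. CPM values are mean ± SD over these 2 libraries, and all coordinates are on GRCh38.

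DHT raised known androgen-induced genes in both lines. FKBP5, a co-chaperone gene, rose from 63.9 ± 1.1 to 1772 ± 16.4 CPM in Vc and from 71.5 ± 3.62 to 1778 ± 94.99 CPM in Ver (n = 2). TMPRSS2, a protease gene, rose from 219 ± 10.6 to 799 ± 6.18 CPM in Vc and from 161 ± 1.82 to 694 ± 11.2 CPM in Ver. ERG, the oncogene fused to it, rose from 323 ± 6.94 to 915 ± 10.7 CPM in Vc and from 237 ± 5.16 to 820.2 ± 8.54 CPM in Ver. The growth-promoting gene MYC fell from 378 ± 8.49 to 52.7 ± 2.01 CPM in Vc and from 319 ± 5.56 to 41.7 ± 1.97 CPM in Ver. UGT2B15, whose enzyme tags DHT for removal, fell from 45.4 ± 5.07 to 2.32 ± 1.13 CPM in Vc and from 85.1 ± 2.29 to 6.17 ± 0.02 CPM in Ver, though its reads can be shared with close paralogs. The log2 change of FKBP5 was 4.79 (SE 0.075, adjusted p = 4.8e-30) in Vc and 4.63 (SE 0.075, adjusted p = 1.2e-29) in Ver. MYC changed by -2.84 (SE 0.062, adjusted p = 3.7e-85) and -2.93 (SE 0.065, adjusted p = 5.5e-85). The prostate protease genes KLK2 and KLK3 rose by 1.21 and 1.46 log2 units in Vc and by 1.08 and 1.19 in Ver.

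The main genes lie as follows: FKBP5 (ENSG00000096060, chromosome 6, 35573585 to 35728583), TMPRSS2 (ENSG00000184012, chromosome 21, 41464551 to 41531116), ERG (ENSG00000157554, chromosome 21, 38380027 to 38661780), MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) and UGT2B15 (ENSG00000196620, chromosome 4, 68646630 to 68670628). Counting was unstranded, so reads of genes that overlap these on the other strand cannot be separated from theirs.

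DHT also moved whole programmes of genes in both lines. Of the 36 androgen-induced genes tested, 32 rose and 3 fell in Vc, with the same counts in Ver and when adjusted over the list alone. All 18 endoplasmic reticulum stress genes, only some of which help fold secreted proteins, rose in both lines (adjusted over the list alone: 18 and 18). DNAJB9, a co-chaperone gene of that compartment, rose from 21.2 ± 0.5 to 156 ± 9.9 CPM in Vc. Of 23 cholesterol synthesis genes 22 rose in each line, also adjusted over the list alone. Of 14 fatty acid synthesis genes 12 rose in each line, also adjusted over the list alone, among them the synthase gene FASN, from 977 ± 36.7 to 3534 ± 40.2 CPM in Vc. The cell-cycle genes moved the other way. Of 25 DNA replication and G1/S genes 20 fell in Vc and 21 in Ver (21 in each adjusted over the list alone), while 2 rose in Ver. MCM4, part of the replicative helicase, fell from 110.1 ± 0.23 to 27.4 ± 0.33 CPM in Vc and from 115 ± 5.79 to 27.7 ± 0.93 CPM in Ver. Of 25 mitosis genes 19 fell in Vc and 17 in Ver (adjusted over the list alone: 20 and 17). Of 12 androgen-repressed genes 10 fell in each line (11 adjusted over the list alone). Of 11 glucocorticoid receptor target genes 10 rose in Vc and 11 in Ver, also adjusted over the list alone. FKBP5, SGK1 and ZBTB16 are in this list and in the androgen-induced list, so these lists are not independent.

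The set tests of these lists in Vc were passed with median log2 changes of 1.48 for androgen-induced genes (adjusted p = 3.1e-27), 1.86 for endoplasmic reticulum stress (4.4e-26), 1.33 for cholesterol synthesis (2.0e-23) and 1.12 for fatty acid synthesis (6.0e-14). They were also passed with medians of -1.59 for androgen-repressed genes (4.4e-11), 1.52 for glucocorticoid receptor targets (2.6e-09) and -1.30 for DNA replication (6.2e-11). The medians in Ver were 1.34, 1.77, 1.19, 0.86, -1.47, 1.497 and -1.33 in that order. Each of these calls held in both lines when the correlation between genes was estimated (adjusted p from 0.00336 to 0.00918). The mitosis list passed with the preset correlation (median -0.63 in Vc, adjusted p = 5.8e-05) but not with an estimated one (adjusted p = 0.158). So did the epithelial and luminal list (0.41, 6.8e-04, with an estimated correlation 0.0748), the neuroendocrine and neural list (-0.58, 0.0336, estimated 0.122) and the mitochondrially encoded list (-0.20, 9.1e-04, estimated 0.453). The UGT2B glucuronidation list was likewise lost (-2.17, 0.0357, estimated 0.231). Without Vc control replicate 1 the UGT2B list was not called in Vc (adjusted p = 0.0710).

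The remaining lists did not pass the test for DHT in Vc. Their median log2 changes were -0.44 for androgen synthesis and metabolism (adjusted p = 0.800), 0.19 for basal prostate (0.884), -0.097 for interferon response (0.905), 0.22 for hypoxia and glycolysis (0.0982) and 0.45 for drug efflux and xenobiotic genes (0.218). WNT and stem cell genes had a median of -0.33 (0.396), stromal and endothelial markers -0.38 (0.292) and heat shock genes 0.23 (0.501). In 3 lists the median and the mean had opposite signs: steroid receptors (0.26 and -0.43, adjusted p = 0.893), mesenchymal transition (-0.72 and 0.43, 0.948) and polyamine and prostate secretory genes (0.31 and -0.26, 0.651). The test pointed upward in all 3. The immune marker list had 2 tested members and was not tested.

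Among the largest single changes, STEAP4, an androgen-induced metalloreductase gene, rose from 1.13 ± 0.15 to 84.6 ± 0.79 CPM in Vc and from 0.23 ± 0.05 to 80.3 ± 5.41 CPM in Ver. Its log2 change was 6.21 (SE 0.28, adjusted p = 1.3e-67) in Vc and 8.36 (SE 0.65, adjusted p = 2.3e-68) in Ver, a difference of 2.15 (SE 0.70, adjusted p = 0.0173); the Ver controls held 5 reads of it in all. The adjusted p of this difference was 0.164 without Vc control replicate 1, 0.164 without Ver control replicate 1 and 0.130 without Ver control replicate 2, and 0.0697 with DESeq2. The signalling gene WNT2 fell from 62.0 ± 3.74 to 1.78 ± 1.08 CPM in Vc and from 83.7 ± 2.39 to 1.04 ± 0.09 CPM in Ver, by -5.05 and -6.31 log2 units. NCAPD3, a condensin subunit gene, rose from 88.5 ± 4.18 to 1589 ± 54.4 CPM in Vc. In all, 9987 genes were called in Vc (4917 higher, 5070 lower) and 9936 in Ver (4772 higher, 5164 lower), of 22553 tested. At least a 2-fold change was seen for 1609 higher and 2407 lower genes in Vc, and for 1438 and 2468 in Ver. Of the called genes, 3915 were higher in both lines (1040.4 would be shared if the lists were independent) and 3825 lower in both (1161). Another 26 were called in opposite directions. Across all tested genes the log2 changes in the 2 lines had Pearson's r = 0.756 and Spearman's rho = 0.744; genes are not independent replicates. No library is shared between these 2 contrasts. Pearson's r depended on the genes kept: it was 0.336 with no low-count filter (40888 genes) and higher for genes of at least 5 CPM.

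**Figure D1:**
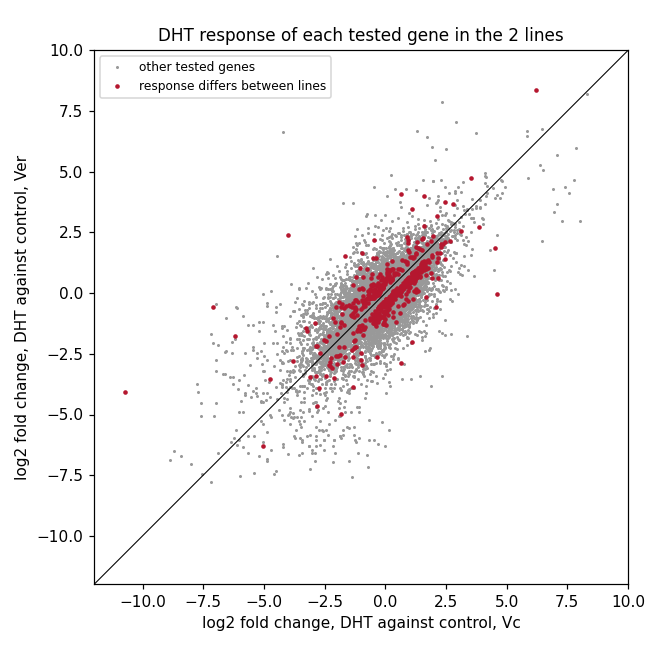
Log2 change with DHT in Vc (x axis) against that in Ver (y axis), one point per tested gene; red points are genes whose responses differed between the lines at an adjusted p under 0.05. Most genes lie along the diagonal, with 523 red points.

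The difference in DHT response between the lines involved far fewer genes than the response itself. AKAP12, which encodes a scaffold for protein kinase A, had 31.9 ± 0.92 CPM in control and 18.8 ± 0.45 CPM with DHT in Vc, but 19.6 ± 1.05 and 38.8 ± 0.68 CPM in Ver. GPX3, a secreted glutathione peroxidase gene, had 30.1 ± 0.21 and 40.7 ± 2.77 CPM in Vc, against 262 ± 9.86 and 115 ± 9.66 CPM in Ver. DSEL, an epimerase gene of dermatan sulfate synthesis, had 119.9 ± 6.34 and 28.1 ± 2.04 CPM in Vc, against 207 ± 3.87 and 18.2 ± 2.49 CPM in Ver. Of the 36 androgen-induced genes 6 were higher and 5 lower in Ver (8 and 8 adjusted over the list alone), and the list did not pass (adjusted p = 0.0945). SLC45A3, a prostate-specific transporter gene, reached 1622 ± 2.32 CPM with DHT in Vc and 1014 ± 42.2 CPM in Ver from similar controls (509 ± 25.1 and 489 ± 34.7 CPM). ZBTB10, a zinc-finger gene, rose more in Ver, and ACPP, the prostatic acid phosphatase gene, fell less there. As Ver minus Vc, the log2 differences were 1.74 (SE 0.18, adjusted p = 2.1e-13) for AKAP12, -1.62 (SE 0.11, adjusted p = 6.9e-28) for GPX3, -1.42 (SE 0.12, adjusted p = 5.6e-19) for DSEL and -0.62 (SE 0.068, adjusted p = 1.4e-12) for SLC45A3. They were 0.40 for ZBTB10 (adjusted p = 5.4e-05) and 0.56 for ACPP (2.7e-12). DESeq2 called 344 genes for this difference. With edgeR 523 genes were called in all (201 higher, 322 lower), 45 and 44 of them by at least 2-fold. That count was 318 without Vc control replicate 1, 323 without Vc DHT replicate 2, 300 without Ver control replicate 2 and 325 without Ver DHT replicate 2.

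Enzalutamide alone, with no androgen added, lowered androgen-induced genes slightly in both lines. PMEPA1, an androgen-induced gene that restrains TGF-beta signalling, fell from 761 ± 27.4 to 469.8 ± 9.88 CPM in Vc and from 1057 ± 43.9 to 551 ± 33.3 CPM in Ver. TMPRSS2 fell from 219 ± 10.6 to 169.7 ± 9.09 CPM in Vc and from 161 ± 1.82 to 115 ± 8.63 CPM in Ver, and ERG from 323 ± 6.94 to 236 ± 1.52 CPM and from 237 ± 5.16 to 152 ± 2.26 CPM. SLC45A3 fell to 373 ± 9.01 CPM in Vc and 273 ± 10.7 CPM in Ver, from the control values 509 ± 25.1 and 489 ± 34.7 CPM. In Vc the ligand gene SHH rose from 159 ± 0.94 to 233 ± 3.22 CPM, and FBLN2, a matrix protein gene, from 188 ± 5.5 to 249.7 ± 1 CPM. In Ver the topoisomerase gene TOP2A rose from 63.5 ± 3.83 to 86.6 ± 1.81 CPM. The log2 changes in Vc were -0.70 (SE 0.047, adjusted p = 1.0e-26) for PMEPA1, -0.45 (SE 0.052, adjusted p = 4.0e-11) for ERG and 0.55 (SE 0.070, adjusted p = 1.3e-09) for SHH. In Ver they were -0.94 (SE 0.047, adjusted p = 1.7e-39) for PMEPA1, -0.64 (SE 0.055, adjusted p = 1.3e-18) for ERG and 0.45 (SE 0.079, adjusted p = 4.0e-05) for TOP2A. In Vc 121 genes were called (35 higher, 86 lower) and in Ver 255 (106 higher, 149 lower). The Vc count was 57 without Vc control replicate 1, 62 without Vc control replicate 2, 61 without Vc enzalutamide replicate 1 and 47 without Vc enzalutamide replicate 2. The Ver count was 112 without Ver control replicate 2, 122 without Ver enzalutamide replicate 1 and 159 without Ver enzalutamide replicate 2. Called in both lines were 40 lower genes (0.568 would be shared by independent lists) and 14 higher genes (0.165). Across all tested genes, most of them not called, the log2 changes in the 2 lines had Pearson's r = 0.0403.

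By lists, the androgen-induced genes were lower with enzalutamide alone in both lines, with a median log2 change of -0.16 in Vc (adjusted p = 1.7e-21, with an estimated correlation 0.00678) and -0.15 in Ver (1.9e-27, estimated 0.00410). Of the 36 genes 8 fell in Vc and 10 in Ver; adjusted over the list alone, 13 and 14 fell and 1 rose in Vc. The endoplasmic reticulum stress genes had a median of -0.25 in Ver, with 8 of 18 lower (12 adjusted over the list alone; adjusted p = 8.8e-23, with an estimated correlation 0.0111). In Vc their median was -0.14, with 3 of 18 lower (7 adjusted over the list alone); that call was made with the preset correlation (1.4e-10) and lost with an estimated one (0.0698). The mitosis genes had a median of 0.26 in Ver (1.1e-11, estimated 0.0299); 1 of 25 was called higher over all genes and 9 adjusted over the list alone. In Vc the mitosis median was -0.14 (adjusted p = 0.0195, with an estimated correlation 0.368). The Vc call had an adjusted p of 0.228 without Vc control replicate 2 and 0.236 without Vc enzalutamide replicate 2. The difference between the lines for mitosis genes had a median of 0.42 (adjusted p = 1.7e-14, with an estimated correlation 0.0180), with 7 of 25 genes higher adjusted over the list alone and 0 over all genes. In untreated cells these genes were lower in Ver than in Vc, and the same control libraries enter this difference.

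For the difference in enzalutamide response between the lines, 5 genes were called, all lower in Ver. TRPM8, an androgen-regulated ion channel gene, went from 90.3 ± 0.06 to 66.6 ± 4.19 CPM in Vc and from 20.4 ± 2.61 to 8.32 ± 1.24 CPM in Ver, a log2 difference of -0.86 (SE 0.15, adjusted p = 0.00117). The difference was -0.39 (SE 0.070, adjusted p = 0.00138) for SLC45A3, -0.68 (SE 0.15, adjusted p = 0.0381) for RELN, a secreted matrix protein gene, -0.86 (SE 0.19, adjusted p = 0.0381) for AP5Z1, an adaptor complex gene, and -0.59 (SE 0.13, adjusted p = 0.0429) for MIB2, a ubiquitin ligase gene. No gene was called higher, but the direction was not firm: 4 of 10 calls were higher with only the groups of the contrast, 1 of 4 without Vc control replicate 2 and 2 of 3 without Ver enzalutamide replicate 2. Over all genes 1374 genes had an unadjusted p under 0.05 in either direction, and DESeq2 called 2 genes. These calls were fragile. The adjusted p of TRPM8 was 0.104 without Ver control replicate 1 and 0.242 without Ver enzalutamide replicate 2, and that of SLC45A3 was 0.0751 without Vc control replicate 1, 0.0641 without Vc enzalutamide replicate 2, 0.234 without Ver control replicate 2 and 0.0800 without Ver enzalutamide replicate 1. RELN was lost without any one of the 8 libraries of the contrast (adjusted p from 0.0568 to 0.385). AP5Z1 was lost without any but Vc enzalutamide replicate 2 (0.0306 to 0.546 over the 8 libraries) and MIB2 without any but Vc control replicate 2 (0.0355 to 0.469). DESeq2 gave 0.668, 0.668 and 1 for these 3 genes, and DESeq2-type size factors 0.0611 for MIB2. The count was 1 without Vc control replicate 1 or Ver control replicate 1 or Ver control replicate 2 or Ver enzalutamide replicate 1, 2 without Vc enzalutamide replicate 1 or Vc enzalutamide replicate 2 and 3 without Ver enzalutamide replicate 2.

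With enzalutamide on top of DHT, the androgen response was weaker than with DHT alone in both lines. The labels give the same 24 h treatment for both compounds, so reversal of an established response was not tested. FKBP5 went from 1772 ± 16.4 with DHT to 241 ± 17.7 CPM with both in Vc, and from 1778 ± 94.99 to 132 ± 24.9 CPM in Ver. TMPRSS2 fell to 352 ± 8.66 CPM in Vc and 224 ± 25.5 CPM in Ver, from 799 ± 6.18 and 694 ± 11.2 CPM. ERG fell from 915 ± 10.7 to 556 ± 0.27 CPM in Vc and from 820.2 ± 8.54 to 373 ± 42.4 CPM in Ver. MYC rose from 52.7 ± 2.01 to 206 ± 2.33 CPM in Vc and from 41.7 ± 1.97 to 227 ± 17.0 CPM in Ver. The log2 changes in Vc were -2.88 (SE 0.067, adjusted p = 1.8e-24) for FKBP5, -0.72 (SE 0.050, adjusted p = 3.6e-27) for ERG and 1.97 (SE 0.063, adjusted p = 5.0e-63) for MYC. In Ver they were -3.75 (SE 0.071, adjusted p = 4.9e-27), -1.14 (SE 0.051, adjusted p = 1.4e-45) and 2.45 (SE 0.066, adjusted p = 6.9e-73). The cytokine receptor gene LIFR changed by -1.80 and -2.31 log2 units, and UGT2B15 by 2.58 and 3.02. In Vc 5059 genes were called (2588 higher, 2471 lower) and in Ver 6076 (3098 higher, 2978 lower).

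Several of the programmes that DHT moved were moved less with both compounds. Of 36 androgen-induced genes 26 fell and 5 rose in Vc, and 28 fell and 4 rose in Ver; adjusted over the list alone, 27 and 28 fell and 5 rose in each. All 18 endoplasmic reticulum stress genes fell in both lines, also adjusted over the list alone, and of 11 glucocorticoid receptor targets 9 fell in Vc and 10 in Ver, also adjusted over the list alone. The median log2 changes in Vc and Ver were -0.67 and -0.84 for androgen-induced genes (adjusted p = 1.7e-20 and 3.0e-24), -0.54 and -0.59 for endoplasmic reticulum stress (5.8e-19 and 5.8e-19) and -1.07 and -1.13 for glucocorticoid receptor targets (8.1e-14 and 4.6e-13). With an estimated correlation these calls held, at 0.00743 and 0.00481, 0.0185 and 0.0185, and 0.00336 and 0.00336. DNA replication genes rose by a median of 0.42 in Vc (adjusted p = 2.2e-04, with an estimated correlation 0.0636, so lost) and 0.57 in Ver (7.8e-07, estimated 0.0198). Androgen-repressed genes rose by medians of 1.01 and 0.85 (1.3e-10 and 8.7e-09, estimated 0.00336 and 0.00410). Cholesterol synthesis genes fell by medians of -0.31 in Vc (2.7e-10, estimated 0.0299) and -0.22 in Ver (4.2e-05), and the Ver call was lost with an estimated correlation (0.124). Fatty acid synthesis genes had medians of -0.30 in Vc (6.9e-08, estimated 0.0340) and -0.32 in Ver (5.0e-05, estimated 0.0903, so lost).

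Over genes, 4569 of the 9987 DHT-called genes in Vc (45.7%) were called the other way when enzalutamide was added, and 5360 of 9936 in Ver (53.9%). Only 50 and 39 were called further in the direction of DHT. For genes picked by the DHT calls of the other line, the shares were 43.4% in Vc and 48.9% in Ver. Across DHT-called genes, Pearson's r between the change with DHT and the change on adding enzalutamide was -0.860 in Vc and -0.899 in Ver. Across all tested genes r was -0.739 (covariance -0.551) and -0.791 (-0.687). Both contrasts use the same DHT libraries, which gives a negative r without any effect. In simulated unchanged groups that shared libraries in this way, the mean r was -0.517 (covariance -0.0710) for Vc and -0.485 (-0.0704) for Ver over 20 draws, so part of the observed r may come from the shared libraries. These values are across genes, and genes are not independent replicates.

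Enzalutamide pushed several androgen-induced genes further down in Ver than in Vc. With both compounds FKBP5 was at 241 ± 17.7 CPM in Vc and 132 ± 24.9 CPM in Ver, although DHT alone gave 1772 ± 16.4 and 1778 ± 94.99 CPM. STEAP4 was at 18.2 ± 0.64 CPM in Vc and 6.78 ± 2.03 CPM in Ver, against 84.6 ± 0.79 and 80.3 ± 5.41 CPM with DHT alone. ZBTB16, a transcription factor gene induced by androgen, was at 188 ± 8.86 and 133 ± 1.7 CPM, against 393 ± 7.89 and 407 ± 3.68 CPM. MYC was higher with both compounds in Ver, at 227 ± 17.0 CPM against 206 ± 2.33 CPM in Vc. CYP1A1, a xenobiotic-metabolizing enzyme gene, had 16.5 ± 2.09 CPM with DHT and 13.1 ± 0.09 CPM with both in Vc, and 25.6 ± 1.18 and 6.04 ± 1.29 CPM in Ver. As Ver minus Vc, the log2 differences were -1.35 (SE 0.20, adjusted p = 5.5e-07) for STEAP4, -0.55 (SE 0.078, adjusted p = 2.6e-07) for ZBTB16, -0.45 (SE 0.076, adjusted p = 2.1e-05) for TMPRSS2, -0.42 (SE 0.071, adjusted p = 3.6e-05) for ERG and 0.48 (SE 0.091, adjusted p = 2.8e-04) for MYC. They were -1.75 for CYP1A1 (adjusted p = 3.1e-08), 1.30 for the secreted phospholipase gene PLA2G2A (1.3e-07) and 1.21 for the ligand gene IHH (2.6e-06). For FKBP5 the difference was -0.87 (SE 0.098, adjusted p = 2.1e-06), but the adjusted p was 0.176 when only the groups of the contrast were fitted. The androgen-induced list had a median difference of -0.25 (adjusted p = 1.4e-13, with an estimated correlation 0.0204), with 11 of 36 genes lower and 1 higher (18 and 1 adjusted over the list alone). In all, 291 genes were called (144 higher, 147 lower), 23 and 17 of them by at least 2-fold. That count was 128 without Vc DHT plus enzalutamide replicate 1, 150 without Vc DHT replicate 1, 169 without Vc DHT replicate 2, 93 without Ver DHT plus enzalutamide replicate 1 and 142 without Ver DHT replicate 2.

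**Figure D2:**
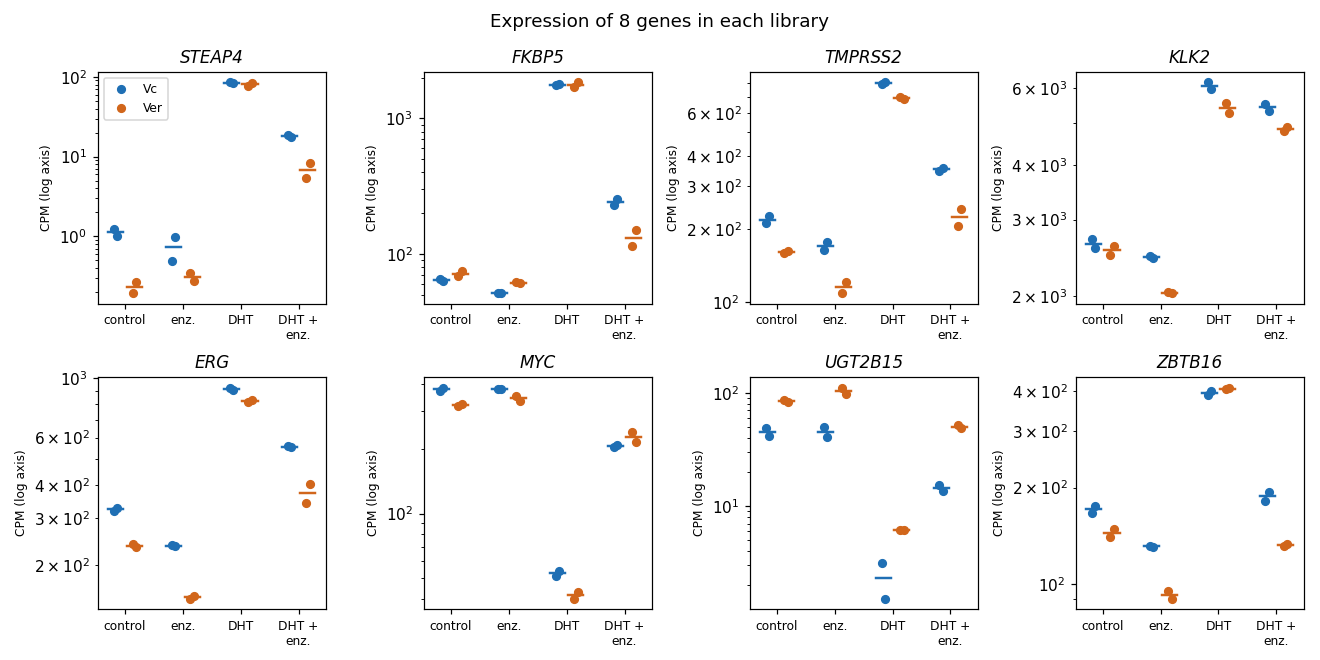
CPM on a log axis for 8 genes in each library, by treatment, with lines through the group means; Vc is blue and Ver orange. FKBP5 and TMPRSS2 are highest with DHT and lower in Ver than in Vc with DHT plus enzalutamide.

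**Figure D3:**
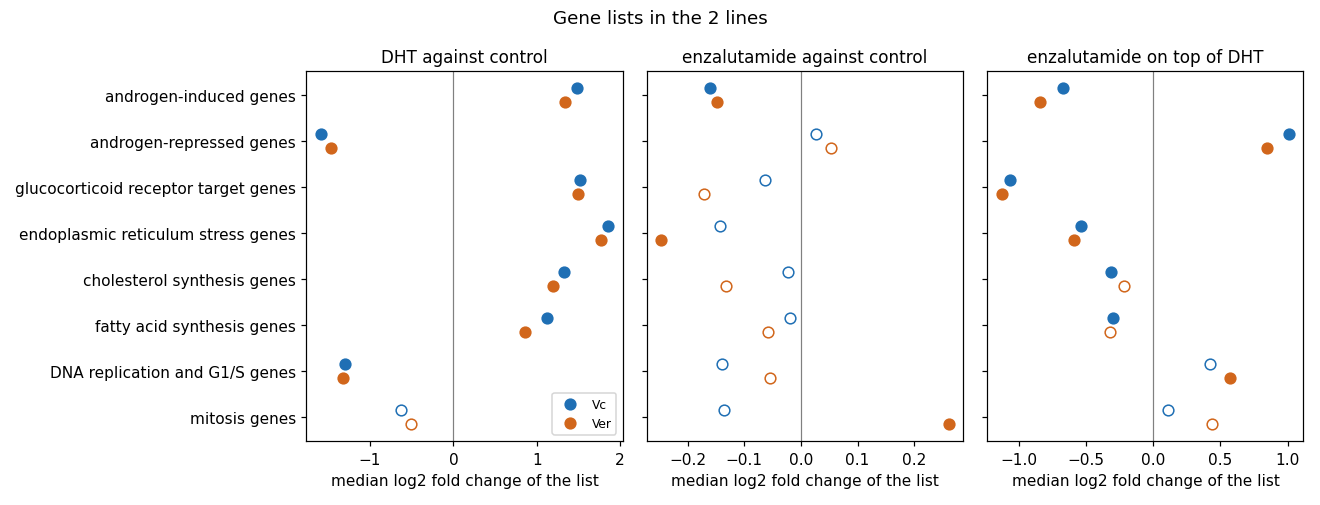
Median log2 change of 8 gene lists in Vc and Ver for DHT against control, enzalutamide against control and enzalutamide on top of DHT; filled symbols are lists with an adjusted p under 0.05 with an estimated correlation. The androgen-induced median is 1.48 in Vc and 1.34 in Ver with DHT.

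With both compounds the cells did not match the untreated state. With DHT plus enzalutamide, FKBP5 stayed above its control in both lines, at 241 ± 17.7 against 63.9 ± 1.1 CPM in Vc and 132 ± 24.9 against 71.5 ± 3.62 CPM in Ver. KLK2, a prostate protease gene, stayed at 5428 ± 134 against 2640.1 ± 89.6 CPM in Vc and 4843 ± 68.7 against 2547 ± 80.9 CPM in Ver. The log2 changes from control were 1.91 (SE 0.077, adjusted p = 3.4e-19) for FKBP5 and 1.04 (SE 0.041, adjusted p = 3.3e-52) for KLK2 in Vc, and 0.88 (SE 0.081, adjusted p = 2.8e-10) and 0.93 (SE 0.041, adjusted p = 2.6e-46) in Ver. In all, 6418 genes were called in Vc (3451 higher, 2967 lower) and 5117 in Ver (2788 higher, 2329 lower). The share of the DHT effect that remained was taken as the log2 change with both compounds divided by that with DHT. It was 39.9% in Vc and 19.0% in Ver for FKBP5, 36.8% in Vc and 22.7% in Ver for TMPRSS2, 52.1% in Vc and 36.6% in Ver for ERG and 86.2% in Vc and 85.4% in Ver for KLK2. For ZBTB16, chosen after its value was seen, it was 11.4% in Vc and -8.00% in Ver. Over the 32 androgen-induced genes that rose with DHT in both lines, its median was 62.6% in Vc and 46.8% in Ver, and it was lower in Ver for 28 of them; this share itself was not tested.

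Several lists were still away from control with both compounds; the share that each list kept was not tested. The cholesterol synthesis genes had medians of 1.03 in Vc and 0.98 in Ver with both compounds (adjusted p = 1.8e-32 and 4.9e-37, with an estimated correlation 0.00336 and 0.00336). The endoplasmic reticulum stress genes had medians of 1.20 and 1.07 (3.2e-34 and 4.9e-37, estimated 0.00425 and 0.00410). The DNA replication genes had medians of -0.87 and -0.72 (4.9e-15 and 1.3e-14, estimated 0.00410 and 0.00410), and fatty acid synthesis genes of 0.91 and 0.75 (2.7e-19 and 1.1e-19, estimated 0.00410 and 0.00410). For androgen-induced genes they were 0.75 and 0.54 (2.2e-31 and 6.4e-20, estimated 0.00410 and 0.00757) and for androgen-repressed genes -1.37 and -1.14 (6.7e-13 and 2.7e-12, estimated 0.00336 and 0.00336). Glucocorticoid receptor targets had 0.63 in Vc (6.4e-05, estimated 0.0187) and 0.42 in Ver (0.00200), and the Ver call was lost with an estimated correlation (0.0529).

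The untreated lines differed from each other in many genes. GPX3 had 262 ± 9.86 CPM in Ver and 30.1 ± 0.21 CPM in Vc. BCAT1, an amino acid transaminase gene, had 15.9 ± 2.69 and 0.97 ± 0.07 CPM. SULT1C2, a sulfotransferase gene, had 1.25 ± 0.39 CPM in Ver and 23.8 ± 1.88 CPM in Vc, and CD44, an adhesion receptor gene, 41.4 ± 0.65 and 142 ± 1.62 CPM. NR3C1, which encodes the glucocorticoid receptor, had 10.9 ± 2.4 CPM in Ver and 4.11 ± 0.4 CPM in Vc. UGT2B15 had 85.1 ± 2.29 and 45.4 ± 5.07 CPM. As Ver minus Vc, the log2 differences were 3.12 (SE 0.075, adjusted p = 2.9e-80) for GPX3, 4.02 (SE 0.34, adjusted p = 5.2e-28) for BCAT1, -4.23 (SE 0.30, adjusted p = 4.0e-36) for SULT1C2 and -1.77 (SE 0.074, adjusted p = 5.8e-50) for CD44. They were 1.40 (SE 0.23, adjusted p = 1.5e-07) for NR3C1 and 0.90 (SE 0.096, adjusted p = 9.1e-15) for UGT2B15. TMPRSS2 and ERG were lower in Ver, by -0.45 and -0.45 log2 units, and KLK3 higher by 0.54. The positions of the main genes are: GPX3 (ENSG00000211445, chromosome 5, 151020438 to 151028993), NR3C1 (ENSG00000113580, chromosome 5, 143277931 to 143435512) and CD44 (ENSG00000026508, chromosome 11, 35138870 to 35232402). All Vc libraries were sequenced in lane 8 and all Ver libraries in lane 2, so line and lane cannot be told apart in this comparison; effects of lane that add on the log scale cancel in the comparisons within a line and in the differences between lines.

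In all, 4252 genes were called (2058 higher in Ver, 2194 lower), 376 and 382 by at least 2-fold; the count was 2828 without Ver control replicate 2. With DHT, with enzalutamide and with both compounds the counts were 3895, 3736 and 4584. Called in the same direction under all 4 treatments were 622 genes higher and 840 lower in Ver. Of 6 UGT2B glucuronidation genes 5 were higher in Ver, also adjusted over the list alone (median 1.32, adjusted p = 5.9e-05, with an estimated correlation 0.0400). The mitosis genes had a median of -0.46 with 13 of 25 lower (15 adjusted over the list alone), a call made with the preset correlation (1.0e-07) and lost with an estimated one (0.0748). Neighbouring genes often differed together: of 265 windows of 10 Mb, 35 had a median difference beyond 0.25 log2 units, 12 higher and 23 lower in Ver. On chromosome 12 the medians of the windows from 1 to 60000000 ranged from 0.29 to 0.62, and on chromosome 2 those from 150000001 to 220000000 ranged from -0.50 to -0.30.

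**Figure D4:**
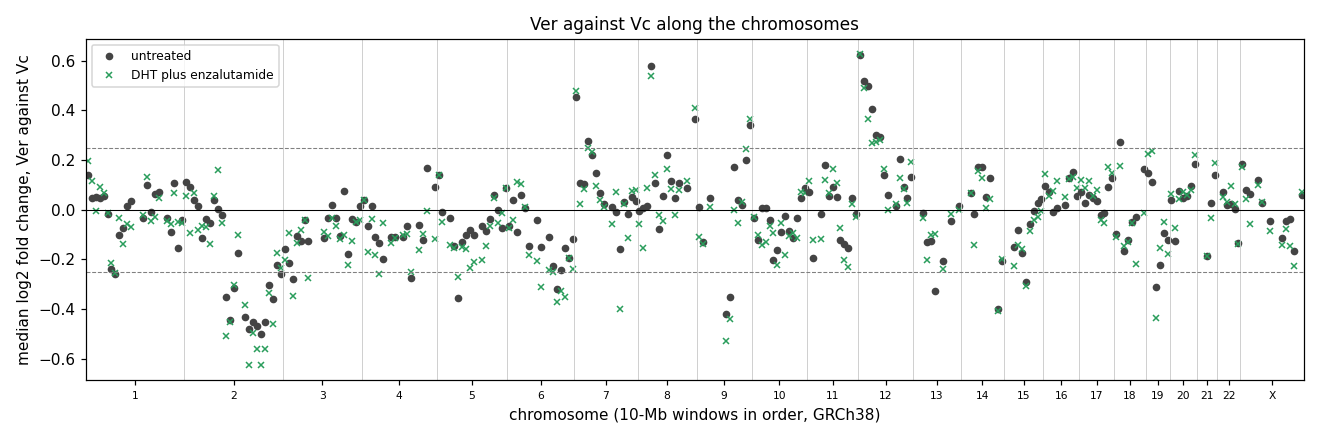
Median log2 difference of Ver against Vc in windows of 10 Mb along the chromosomes, for untreated cells (dots) and cells with DHT plus enzalutamide (crosses); dashed lines mark 0.25 log2 units on either side of 0. Runs of neighbouring windows on chromosomes 2 and 12 lie beyond the dashed lines.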

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

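The fits of gene lists that leave out 1 library were chosen only after the data were seen. The tests of differences between the lines were fixed before. The checks of 3 explanations for the androgen-induced list addressed a pattern found in these data. What each explanation predicts was written before its check. Every result here is a difference between the responses of Vc and Ver to the same treatment, found by testing that difference itself. With enzalutamide on top of DHT, androgen-induced genes were lowered further in Ver than in Vc, with a median log2 difference of -0.25 over 36 genes. Of 3 explanations examined, the tables argue against library size and against a single deciding library. Thinning all libraries to the smallest gene total left a mean median of -0.22 (SD 0.028 over 10 draws), so library size is not the cause. The median stayed at -0.17 or lower without any one of the 8 libraries; without Ver DHT plus enzalutamide replicate 1 it was nearest to 0. Its percentile was 0 among 10000 random lists matched for level and DHT response, whose median was -0.074 (95% between -0.16 and 0.011). The random genes were drawn independently, so this range leaves out correlation between genes regulated together and may be too narrow. The list lay below the matched lists, but this cannot exclude that it followed other DHT-raised genes. Other technical causes, such as a difference in dosing, the lower share of reads in no gene in Ver or a lane effect that does not cancel, were not excluded. This contrast does not use the controls, and the lines already differed when untreated and in parts of the DHT response. Whether those differences contribute to the list's median was not tested. Of 32 androgen-induced genes raised by DHT in both lines, 28 kept a smaller share of the DHT effect in Ver, which was not tested either. A stronger block of androgen-induced genes after long exposure to the drug is a hypothesis for these values. No protein and no binding to DNA was measured. The series holds only 2 lines, Vc and Ver. An effect of the drug therefore cannot be told apart from other differences that arose between them.

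The genes behind these differences were named by the rule. For DHT, 523 genes differed, among them the kinase scaffold gene AKAP12 (1.74), the peroxidase gene GPX3 (-1.62), the epimerase gene DSEL (-1.42), the transporter gene SLC45A3 (-0.62), the zinc-finger gene ZBTB10 (0.40), the phosphatase gene ACPP (0.56) and the metalloreductase gene STEAP4 (2.15), as log2 differences of Ver minus Vc. For STEAP4 the adjusted p was 0.164 without Vc control replicate 1, 0.164 without Ver control replicate 1 and 0.130 without Ver control replicate 2, and 0.0697 with DESeq2. The DHT count was 318 without Vc control replicate 1, 323 without Vc DHT replicate 2, 300 without Ver control replicate 2 and 325 without Ver DHT replicate 2. For enzalutamide alone, 5 genes differed: TRPM8 (-0.86), SLC45A3 (-0.39), RELN (-0.68), AP5Z1 (-0.86) and MIB2 (-0.59). The adjusted p of TRPM8 was 0.104 without Ver control replicate 1 and 0.242 without Ver enzalutamide replicate 2, and that of SLC45A3 0.0751 without Vc control replicate 1, 0.0641 without Vc enzalutamide replicate 2, 0.234 without Ver control replicate 2 and 0.0800 without Ver enzalutamide replicate 1. RELN was lost without any one of the 8 libraries, AP5Z1 without any but Vc enzalutamide replicate 2 and MIB2 without any but Vc control replicate 2; the adjusted p ran from 0.0568 to 0.385, 0.0306 to 0.546 and 0.0355 to 0.469. That count was 1 without Vc control replicate 1 or Ver control replicate 1 or Ver control replicate 2 or Ver enzalutamide replicate 1, 2 without Vc enzalutamide replicate 1 or Vc enzalutamide replicate 2 and 3 without Ver enzalutamide replicate 2. For enzalutamide on top of DHT, 291 genes differed. Androgen-induced genes lower in Ver were FKBP5 (-0.87), TMPRSS2 (-0.45), ERG (-0.42), STEAP4 (-1.35) and ZBTB16 (-0.55), as was the enzyme gene CYP1A1 (-1.75). For FKBP5 the adjusted p was 0.176 when only the groups of the contrast were fitted. The difference was positive for MYC (0.48). The difference was also positive for the phospholipase gene PLA2G2A (1.30) and the ligand gene IHH (1.21). That count was 128 without Vc DHT plus enzalutamide replicate 1, 150 without Vc DHT replicate 1, 169 without Vc DHT replicate 2, 93 without Ver DHT plus enzalutamide replicate 1 and 142 without Ver DHT replicate 2.

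By gene lists, 17 differences between the lines passed with the preset correlation and 2 with an estimated one: androgen-induced genes with enzalutamide on top of DHT (-0.25, estimated 0.0204) and mitosis genes with enzalutamide alone (0.42, estimated 0.0180). In untreated cells the mitosis genes were lower in Ver than in Vc, a call lost with an estimated correlation (0.0748). The same controls enter the mitosis difference, so low Ver controls would also raise it. Whether they did was not tested. The other 15 differences did not pass with an estimated correlation. For DHT they were cholesterol synthesis genes (-0.19, adjusted p = 4.3e-06, estimated 0.0903), mitochondrially encoded genes (0.10, adjusted p = 8.2e-04, estimated 0.453) and heat shock genes (0.085, adjusted p = 0.0456, estimated 0.333), as median log2 differences. For enzalutamide alone they were androgen-induced genes (-0.031, adjusted p = 0.00251, estimated 0.274), cholesterol synthesis genes (-0.11, adjusted p = 0.0120, estimated 0.316), endoplasmic reticulum stress genes (-0.12, adjusted p = 6.2e-04, estimated 0.293), drug efflux and xenobiotic genes (-0.16, adjusted p = 0.0108, estimated 0.236) and mitochondrially encoded genes (0.10, adjusted p = 1.5e-05, estimated 0.333). For enzalutamide on top of DHT they were UGT2B glucuronidation genes (0.79, adjusted p = 0.00713, estimated 0.130), glucocorticoid receptor target genes (-0.094, adjusted p = 0.00203, estimated 0.0529), DNA replication and G1/S genes (0.21, adjusted p = 0.00299, estimated 0.115) and mitosis genes (0.17, adjusted p = 0.00234, estimated 0.268). The others there were endoplasmic reticulum stress genes (-0.082, adjusted p = 0.0148, estimated 0.430), mitochondrially encoded genes (0.20, adjusted p = 1.6e-09, estimated 0.198) and heat shock genes (-0.21, adjusted p = 1.3e-04, estimated 0.0952).

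With the preset correlation, 11 of these 17 differences were lost when 1 library was left out. For mitochondrially encoded genes with DHT the adjusted p was 0.373 without Vc control replicate 1 and 0.261 without Vc DHT replicate 2. It was 0.300 without Vc control replicate 1, 0.113 without Vc DHT replicate 2, 0.0887 without Ver control replicate 2 and 0.0802 without Ver DHT replicate 2 for heat shock genes with DHT. For androgen-induced genes with enzalutamide alone the adjusted p was 0.0762 without Ver enzalutamide replicate 2. It was 0.0609 without Vc control replicate 2, 0.186 without Vc enzalutamide replicate 1, 0.0569 without Ver control replicate 1 and 0.592 without Ver enzalutamide replicate 2 for cholesterol synthesis genes with enzalutamide alone. For endoplasmic reticulum stress genes with enzalutamide alone the adjusted p was 0.0587 without Vc control replicate 2. It was 0.268 without Vc control replicate 2, 0.109 without Vc enzalutamide replicate 1 and 0.0606 without Ver control replicate 1 for drug efflux and xenobiotic genes with enzalutamide alone. For mitochondrially encoded genes with enzalutamide alone the adjusted p was 0.326 without Vc control replicate 1 and 0.517 without Ver enzalutamide replicate 2. It was 0.0797 without Vc DHT replicate 1 for UGT2B glucuronidation genes with enzalutamide on top of DHT. For glucocorticoid receptor target genes with enzalutamide on top of DHT the adjusted p was 0.0529 without Ver DHT plus enzalutamide replicate 1. It was 0.320 without Ver DHT replicate 1 for mitosis genes with enzalutamide on top of DHT. For endoplasmic reticulum stress genes with enzalutamide on top of DHT the adjusted p was 0.596 without Ver DHT plus enzalutamide replicate 1 and 0.0722 without Ver DHT replicate 1.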

How the results depend on the processing

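The count of lists with each library left out and the count of Ver against Vc calls outside shifted windows were chosen only after the data were seen. Of 82 gene results named in the text that DESeq2 gave a value for, 78 kept their direction and call. DESeq2 gave no adjusted p for SHH with enzalutamide in Vc. It also gave none for CYP1A1 and STEAP4 in the difference for enzalutamide on top of DHT. All of these were called by edgeR. Direction and call were kept by 84 of 85 with RLE size factors and by 85 with no low-count filter. They were kept by 84 with only the groups of the contrast and by 85 with the replicate block. None reversed with these. Replicate numbers did not pair the libraries (r between the replicate differences of 2 groups from -0.0231 to 0.0158 within a line, across genes), and the block gave 545 genes for the difference in DHT response.

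The counts for DHT, enzalutamide on top of DHT and DHT plus enzalutamide against control in each line stayed within 1.5 times under every alternative. For the difference in DHT response DESeq2 called 344 genes, and leaving out 1 library gave 300 to 529. For enzalutamide alone leaving out 1 library gave 47 to 62 in Vc and 112 to 174 in Ver. The difference in enzalutamide response had 10 genes with only the groups of the contrast, 2 with DESeq2 and 1 to 4 without 1 library. Without 1 library the difference for enzalutamide on top of DHT had 93 to 357 genes and Ver against Vc 2828 to 3191. Outside shifted windows 3378 Ver against Vc calls were counted, 16.7% of 20184 tested genes, against 36.9% of 2369 inside. The windows were picked on the same untreated fold changes, so a higher share inside was built in. List calls fell from 104 to 46 with an estimated correlation and were 97 to 108 without 1 library. The share of DHT calls reversed by enzalutamide was 34.3 to 50.2% in Vc and 39.2 to 59.2% in Ver without 1 library, lowest without a DHT plus enzalutamide library. Its r over all genes was -0.739 in Vc and -0.791 in Ver, and over DHT-called genes without 1 library -0.901 to -0.792 and -0.926 to -0.827. For these moved values the cause was not tested. The r of the DHT response between lines was 0.925 for genes of at least 5 CPM and 0.336 with no low-count filter (40888 genes; 0.756 on the original genes). It was 0.640 to 0.656 without 1 control or DHT library and 0.700 to 0.705 without 1 of the others. The filter then let in more genes. This is part of the fall without a control or DHT library (24039 genes without Vc DHT replicate 1, with r = 0.696 on the original genes). Without 1 of the others r was 0.756 on the original genes, so the added genes account for that fall. The simulated recovery of a 1.5-fold difference between the lines was 23.9%, with the depth, spread and 2 libraries per group of this series. Few genes were changed in that simulation. Which of these limits the recovery was not tested.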

Other observations

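The tests of chance and of copy number for the chromosome segments were chosen only after the results were seen. So were both tests of the genes lowered by enzalutamide alone. What the test of GC content and gene length predicts was written before it, but it too addressed a pattern found in these data. NPY, a neuropeptide gene of prostate epithelium, was lower with either compound alone but not with both: in Vc it had 252 ± 0.05 CPM in control, 106 ± 1.95 with DHT, 158 ± 5.97 with enzalutamide and 248 ± 2.58 with both, and in Ver 112 ± 3.56, 38.3 ± 1.89, 65.6 ± 2.61 and 129 ± 2.91 CPM (n = 2). TRPM8 was higher with both compounds (249 ± 7.11 CPM in Vc, 71.2 ± 1.06 in Ver) than with DHT alone (167 ± 4.65 and 49.2 ± 4.91 CPM). These profiles over 4 treatments were chosen after their values were seen and were not tested as such.

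Neighbouring genes shifted together between Ver and Vc, as on chromosomes 2 and 12: over 265 windows on all chromosomes examined, the SD of the window medians was 0.172. Correcting for GC content and gene length left 85.4% of the mean shift, so these trends are not the whole cause. Of 10000 shuffles of the genes, 0% gave an SD as large (mean 0.0604, highest 0.0737), which argues against chance clustering. A different DNA copy number of these segments in the 2 lines may explain the pattern as a hypothesis: 100% of the 35 shifted windows kept their sign in all 4 treatments, and the window medians of untreated cells and cells with both compounds had r = 0.923 across windows, which are not independent replicates. DNA was not measured, and line cannot be told apart from lane. Any lasting difference between the lines would also keep its sign, so these values do not set copy number apart from other causes.

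Genes that enzalutamide alone lowered were mostly genes that DHT raised, such as PMEPA1, TMPRSS2 and ERG. Of the 86 genes lower in Vc, 56 were called higher and 19 lower with DHT in Ver, a ratio of 2.95; of the 149 lower in Ver, 117 were higher and 15 lower with DHT in Vc. Taking the DHT calls from the other line removes the control libraries that both contrasts would share, and opposite calls still outnumbered same-direction calls by 2.85 or more (77 against 27, and 196 against 27), which argues against shared libraries. Residual androgen signalling in the hormone-stripped medium may be what enzalutamide blocked, as a hypothesis; androgen in the medium was not measured.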
